A study of Mus musculus with 22 samples.

How the data were processed

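RNA was sequenced from cortical neurons of mouse embryos labelled as lacking Creb1, the gene of the transcription factor CREB. The neurons came from embryonic day 16.5 on a C57BL/6 background and were used at 7 days in vitro. A herpes simplex virus (HSV) vector carried GFP as the control, wild-type CREB (WT), CREB without its glycosylation site (S40A), CREB without its phosphorylation site (S133A), or CREB without either (S40A-S133A). Expression lasted 4 or 8 hours, and all neurons were depolarized for 2 hours with 55 mM KCl in the presence of 1 µM TTX, a sodium channel blocker, and 100 µM D-AP5, an NMDA receptor blocker. The 22 libraries were read on an Illumina instrument.

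The authors deposited 1 table of FPKM values per library, with 24490 gene entries each. Per the submitters' processing notes, the tools were CASAVA 1.7, Bowtie 0.12.2 and Cufflinks with no version given, and the named builds were mm8 and mm10 without a role. The deposited gene positions fall on mm10, and start positions are given here counted from 1. FPKM values hold fragments per length of transcript and relative to library size, so the authors had already divided by transcript length and library size. How reads that match several places were assigned is not given in the sources used here, and genes with near-identical copies may be uncertain for that reason. Strand handling is not given either, so overlapping and antisense genes cannot be told apart.

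Each library's group and replicate number came from the labels. The numbers in the deposited file names put the libraries into sets and, within them, runs, and these are used as technical batches. Replicate 1 of every 4 h group formed run A and replicate 2 run B. At 8 h, replicates 1 and 2 of GFP, WT and S40A formed the earlier set, with runs C1 and C2. Replicates 3 and 4 of those groups, together with replicates 1 and 2 of S133A and S40A-S133A, formed the later set, with runs D1 and D2. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries held identical values.

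The deposited FPKM values were scaled between libraries by median-of-ratios factors, a pseudocount of 1 FPKM was added, and log2 values were taken. All fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 22 libraries numbered 12118. Cufflinks recorded a failed estimate for 23 gene entries, among them Per1, Nsg2 and Dnmt3a. Removing the 21 of these above the minimum left 12097 genes tested, of which 11178 were long genes with an assigned name rather than small RNA entries or predicted genes. Entries with a duplicated symbol numbered 766. The fit used limma 3.58.1 in R 4.3.3 with a mean-variance trend, moderated two-sided tests and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. All 16 libraries at 8 h entered 1 fit with a term for the library set, leaving 10 residual degrees of freedom. The 6 libraries at 4 h entered a separate fit without a batch term, leaving 3, and a joint fit of the 22 libraries, leaving 13, tested whether effects differed between the times. Figures and depth estimates were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene symbols were checked against a GENCODE M21 table of names.

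Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 21 lists that had at least 2 measured genes, and again with a correlation estimated per list and with fry. Fry's directional test asks whether a list's genes move one way on balance, and its mixed test whether they change in either direction. The lists held activity-regulated effectors, immediate early transcription factors, known CREB target genes, signal feedback inhibitors, CREB family members and coactivators, the O-GlcNAc machinery, glycolysis and glucose uptake, nuclear-encoded oxidative phosphorylation, ribosomal proteins, heat shock, unfolded protein and integrated stress, apoptosis and p53, interferon and antiviral genes, and synaptic components. Marker lists covered excitatory neurons, inhibitory neurons, astrocytes and radial glia, oligodendrocyte lineage, microglia, vascular cells and fibroblasts, cell cycle and progenitors, and blood. The blood list had 1 measured gene and the list of mitochondrially encoded genes had 0, so neither was tested. Of the 12 microglia genes, only 2 reached the minimum, and of the 32 interferon genes only 5. In text that gives counts for single genes, "adjusted over the list alone" means a Benjamini-Hochberg adjustment over that list's measured genes.

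The groups, comparisons, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. Named genes were Creb1, then up to 10 called genes with the largest positive and 10 with the largest negative fold change whose groups did not overlap once set means were removed. Where fewer than 10 genes were called, the 10 genes with the smallest p were named as values without a verb of change. From each list with a camera call, the 4 members with the smallest p were named. Duplicated symbols, predicted genes, small RNA entries and genes with a failed estimate were left out of that rule, and the small RNA entries named in the report were therefore chosen after their values were seen. A few genes that the rule names are not reported here. Some choices came later, after results had been seen. These were the alternatives limited to long named genes, the list tests without replicate 2 of GFP at 8 h, the list tests with the run as a block, the follow-up of Pias4 and Gap43 in the closing section, and a limit on which named genes were followed for the time differences.

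The alternatives were the deposited FPKM without further scaling, quantile normalization, a pseudocount of 0.1, a minimum mean of 5 FPKM or none, no set term, the run or the replicate number as a block, each set alone, a joint fit of all libraries, limma with a robust prior or without the trend, split controls, an estimated correlation, fry, and leaving out each library in turn. Replicate numbers were checked for pairing through the correlation of deviations from the group means. At 4 h all 6 pairs of libraries with the same number correlated (r from 0.83 to 0.91), and the number coincides with runs A and B, so the blocked value is given beside a 4 h result where it changes a call or moves a count by over 1.5 times. At 8 h the number matches the run only in GFP, WT and S40A, and its block is only an alternative.

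Depth was read from the low values, since a gene's FPKM steps by what 1 read is worth. Over 2864 genes with a single transcript of 700 to 3000 bp, this gave an estimated 17 to 31 M reads per library (M for mega), with a median of 23 M. In 4 libraries, the 3 of run A at 4 h and replicate 2 of GFP at 8 h, between 3.95% and 7.73% of the low values used lay well below the value of 1 read, against at most 0.717% in the other 18 libraries. An exact 0 can be a failed estimate in files without counts, so such genes are only said to be listed at 0.

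The fitting steps were tested on simulated data with 200 changed genes among the 12097 tested. For WT against GFP at 8 h, 73.1%, 79.1% and 98.5% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered. There, 5.32% of unchanged genes and 130 of 12097 real genes had an unadjusted p under 0.05, so real recovery may be lower. The shares were 44.8%, 79.1% and 95.5% for S133A against WT at 8 h, and 0%, 0% and 36.4% for S40A against WT at 4 h. Each simulation called a list of 40 genes shifted by log2 0.3 and 0 of 5 random lists. Random lists do not test genes that move together.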

Results

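RNA levels are described here for 22 libraries of depolarized cortical neurons labelled as lacking Creb1 that received a virus carrying GFP or 1 of 4 forms of CREB. After 4 h of virus expression there were 2 libraries each for GFP, WT CREB and S40A. After 8 h there were 4 libraries each for GFP, WT CREB and S40A, and 2 each for S133A and S40A-S133A. Each library rested on an estimated 17 to 31 M reads (M for mega). The first 3 principal components held 44.9%, 19.9% and 10% of the variance. At 4 h, libraries of runs A and B lay far apart on the first and second components, each run together whatever virus it had received. The library most like another was usually one of the same run that carried a different virus. Replicate 2 of GFP at 8 h stood apart, with a highest correlation of 0.93 to any other library, against 0.975 to 0.994 for the rest.

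**Figure D1:**
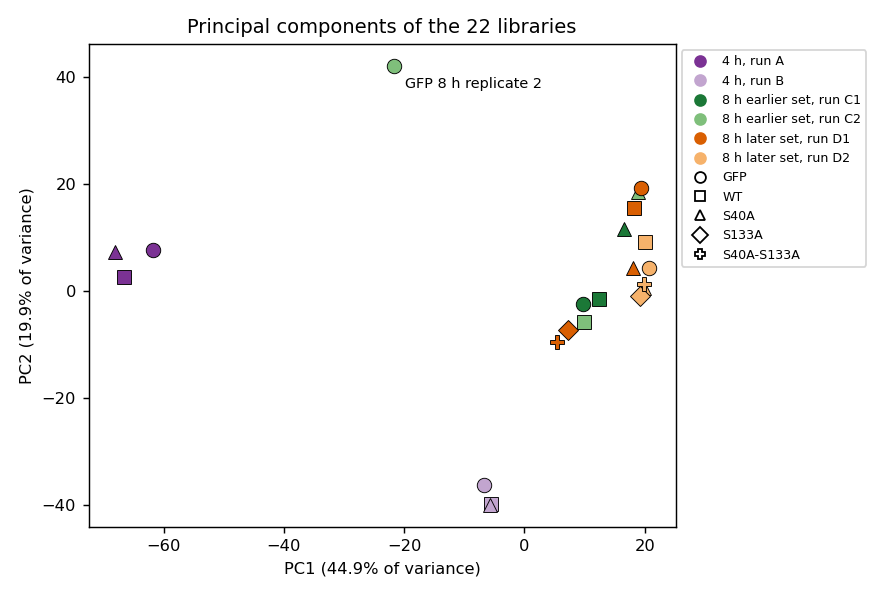
Principal components of the log2(scaled FPKM + 1) values of the 22 libraries, one point per library, with the share of variance on each axis (44.9% on the first and 19.9% on the second). The 4 h libraries of runs A and B form separate groups that each hold all 3 viruses, and replicate 2 of GFP at 8 h lies apart from the other 8 h libraries.

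Creb1 (chromosome 1, 64532804 to 64604548, mm10), the gene supplied by the virus, was reported first because it checks the labels. At 4 h its mean level was 13.9 ± 2.88 scaled FPKM with GFP, 249 ± 0.980 with WT CREB and 252 ± 23.5 with S40A (SD, n = 2 each). At 8 h it was 12.1 ± 2.19 with GFP, 1200 ± 657 with WT CREB and 1230 ± 765 with S40A (SD, n = 4 each), and 1210 ± 923 with S133A and 1410 ± 1050 with S40A-S133A (SD, n = 2 each). Every library with a CREB virus lay above every GFP library of its time point, so no virus label was contradicted. Which part of Creb1 was deleted is not given in the sources used here, and a value for the whole gene can hold reads from the rest of it. The GFP levels therefore do not check the genotype. Within the later 8 h set, Creb1 was 632 ± 90.6 in the 4 CREB libraries of run D1 and 2110 ± 188 in those of run D2, a ratio of 3.34 that was shared by all 4 forms of CREB.

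**Figure D2:**
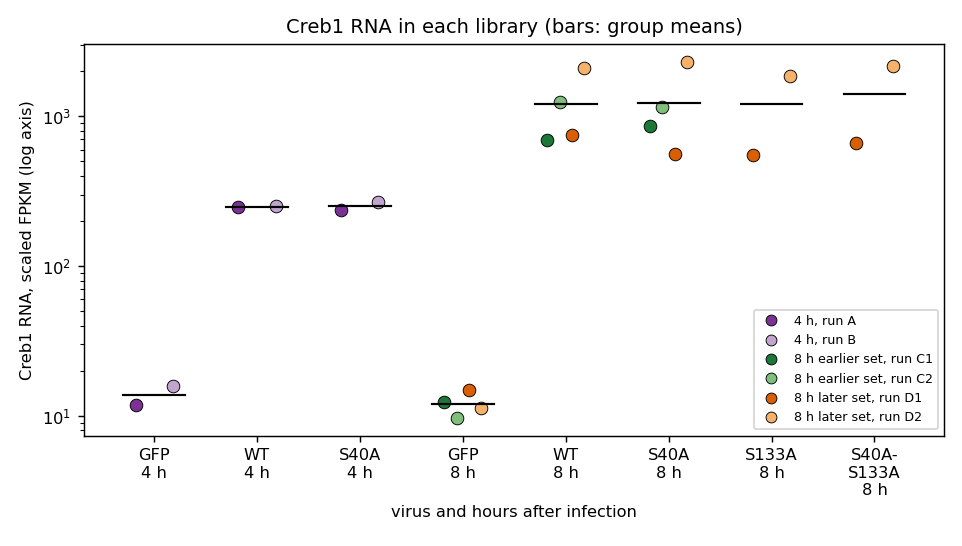
Creb1 in each of the 22 libraries as scaled FPKM on a log axis, by virus and time, with bars at the group means and colours for the runs. GFP libraries averaged 13.9 at 4 h and 12.1 at 8 h, and CREB libraries of the later 8 h set split into values near 632 in run D1 and 2110 in run D2.

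The effect of WT CREB was measured against GFP at 8 h. Creb1 rose 83.7-fold (95% interval 36.9 to 190, adjusted p = 9e-04) and was the only gene called by limma among 12097. At an unadjusted p under 0.05 there were 130 genes (295 with the run as a block), against 605 that chance gives. Gap43 (chromosome 16, 42248561 to 42340651), which encodes a growth cone protein of extending axons, had the smallest p after Creb1 and did not pass the adjustment. It stood at 714 ± 144 scaled FPKM in GFP and 324 ± 85.7 in WT (SD, n = 4 each), with a log2 difference of -1.16 (SE 0.20, adjusted p = 0.57). Its values in the 12 CREB libraries, from 205 to 480, did not overlap those of the 4 GFP libraries, from 557 to 895. Tstd1, a small sulfurtransferase, stood at 0.856 ± 0.261 in GFP and 1.98 ± 0.188 in WT (log2 difference 0.69, adjusted p = 1). Other genes that the rule named, each with an adjusted p of 1, included H1f0, a linker histone, at -0.25, and Hist1h4i, a core histone, at -0.70. Above 0 lay Fundc1, a mitochondrial outer membrane protein, at 0.38, Vkorc1, the vitamin K epoxide reductase, at 0.32, and Tbc1d7, a subunit of the TSC complex, at 0.25. Coro1b and Sap30bp were at -0.17 and -0.15.

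The genes that depolarization and CREB are best known for did not separate WT from GFP at 8 h. Fos stood at 534 ± 221 in GFP and 532 ± 216 in WT, and Npas4 at 138 ± 72.5 and 129 ± 83.9 scaled FPKM (SD, n = 4 each). Nr4a1 stood at 338 ± 194 and 313 ± 188, and Bdnf, a secreted growth factor, at 10.5 ± 7.49 and 9.86 ± 4.88 scaled FPKM (SD, n = 4 each). Of 24 immediate early transcription factors 11 were higher and 13 lower (median log2 difference -0.03, adjusted p = 0.78 by camera). Of 35 known CREB targets 16 were higher and 19 lower (-0.03, 0.81), and of 31 activity-regulated effectors 14 and 17 (-0.02, 0.68). Signal feedback inhibitors divided 11 to 11 (adjusted p = 0.82). In the CREB family and coactivator list Creb1 alone passed, both over all genes and adjusted over the list alone, and the camera test of that list gave an adjusted p of 0.31. Camera called 3 of 21 lists in this comparison. Ribosomal protein genes were lower in 65 of 74 (median -0.55, adjusted p = 8.5e-12, and adjusted p = 0.94 with an estimated correlation), with Rpl9 at -2.06 and Rps27a at -1.14. Glycolysis genes were lower in 15 of 20 (median -0.16, adjusted p = 0.041, and adjusted p = 0.94 with an estimated correlation), with Gapdh at -1.41, Pgam1 at -1.12 and Pgk1 at -0.99. O-GlcNAc genes, which make and use the sugar nucleotide for that modification, were higher in 8 of 9 (median 0.16, adjusted p = 0.041, and adjusted p = 0.94 with an estimated correlation), with Gfpt1, Amdhd2 and Ogt, the transferase itself, each at 0.19. The estimated correlation thus ended all 3 calls, and the run as a block ended those of glycolysis (adjusted p = 0.10) and O-GlcNAc genes (0.084). No member of these lists passed adjusted over the list alone or over all genes.

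Replicate 2 of GFP carried the ribosomal and glycolytic differences. Gapdh was at 132 scaled FPKM in it and 0.86 at the lowest of the GFP libraries, and Rpl9 at 249 against 0.505. Within runs the ribosomal median of WT minus GFP was -2.13 in run C2, which holds that library, and -0.08, -0.03 and -0.03 in runs C1, D1 and D2. That of glycolysis was -0.62 against 0.07, 0.01 and 0. The O-GlcNAc median was 0.10, 0.27, 0.07 and -0.02 in runs C1, C2, D1 and D2. Without that library the ribosomal list had an adjusted p of 0.45, glycolysis 0.55 and the O-GlcNAc list 0.19.

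**Figure D3:**
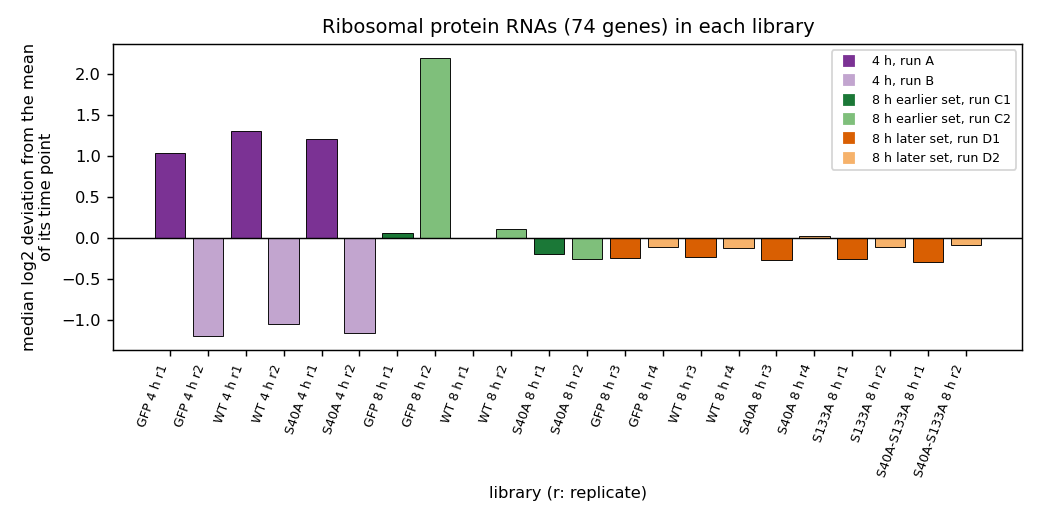
Ribosomal protein genes in each of the 22 libraries, drawn as the median over the 74 genes of the log2 deviation from the gene's mean at that time point, with colours for the runs. Replicate 2 of GFP lies far above the other 8 h libraries, and at 4 h the libraries of run A lie above 0 and those of run B below it.

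The effect of CREB that cannot be glycosylated at S40 was measured against GFP at 8 h. Creb1 rose 82.9-fold (95% interval 36.6 to 188, adjusted p = 0.00092) and was again the only call by limma. There were 717 genes at an unadjusted p under 0.05 (1273 with the run as a block), where chance gives 605. Genes of the respiratory chain stood slightly higher in S40A, 27 of 32 in the oxidative phosphorylation list (median log2 difference 0.12, adjusted p = 8.5e-06 by camera, and adjusted p = 0.92 with an estimated correlation), led by Uqcrc2 at 0.24, Uqcrfs1 at 0.28 and Ndufv2 at 0.23, subunits of complexes III and I. Synaptic components were higher in 25 of 29 (median 0.19, adjusted p = 0.00057, and adjusted p = 0.92 with an estimated correlation). Snap25, a vesicle fusion protein, stood at 131 ± 11.5 in GFP and 157 ± 12.3 in S40A, and Syt1, the calcium sensor of release, at 48.3 ± 10.1 and 66.0 ± 13.0 scaled FPKM (SD, n = 4 each). Inhibitory neuron markers were higher in 13 of 14 (median 0.19, adjusted p = 0.038, and adjusted p = 0.96 with an estimated correlation), including Npy at 0.69, Gad2 at 0.43 and Slc32a1 at 0.41. Heat shock genes were lower in 10 of 12 (median -0.26, adjusted p = 0.026, and adjusted p = 0.92 with an estimated correlation), with the inducible chaperones Hspa1a at -1.12 and Hspa1b at -1.02. Ribosomal protein genes were lower in 69 of 74 (median -0.66, adjusted p = 1.6e-14, and adjusted p = 0.92 with an estimated correlation). None of the 5 calls held with an estimated correlation, and no member passed adjusted over the list alone. Among single genes with the next smallest p were Smim13 at 0.35, Reep5, an endoplasmic reticulum shaping protein, at 0.33, Pias4, a SUMO ligase, at -0.28, and Gap43 at -0.99. Others were Vstm2a at 0.47, Mpv17l at 0.45, Sart3 at -0.27 and Txn1, a thioredoxin, at 0.25, all with an adjusted p of 0.58. Known CREB targets divided 23 higher to 12 lower (adjusted p = 0.45) and immediate early factors 14 to 10 (0.93). In runs C1, C2, D1 and D2 the medians were 0.33, -0.06, 0.11 and 0.08 for oxidative phosphorylation, 0.35, -0.07, 0.21 and 0.02 for synaptic components, and 0.50, -0.13, 0.38 and -0.04 for inhibitory markers. They were -0.09, -1.05, -0.19 and 0.01 for heat shock and -0.26, -2.36, -0.04 and 0.14 for ribosomal proteins. Without replicate 2 of GFP, which is in run C2, the heat shock call was lost (adjusted p = 0.56) and the ribosomal median went to -0.10 (adjusted p = 0.0035).

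S40A and WT CREB were compared directly at 8 h to isolate the S40 site. Their Creb1 levels differed by a factor of 0.991 (95% interval 0.437 to 2.25), and limma called 0 genes. At an unadjusted p under 0.05 there were 514 (897 with the run as a block). Synaptic components were higher in S40A in 27 of 29 (median 0.18, adjusted p = 7.6e-07 by camera, and adjusted p = 0.20 with an estimated correlation), with Syt1 at 0.43, Syp, a vesicle membrane protein, at 0.33, the NMDA receptor subunit Grin1 at 0.32 and Snap25 at 0.20, and the list median was above 0 in 4 of 4 runs, from 0.11 to 0.29. Oxidative phosphorylation genes were higher in 32 of 32 (median 0.13, adjusted p = 6.1e-08, and adjusted p = 0.65 with an estimated correlation), with Ndufa4 at 0.24 and Uqcrc1 at 0.23, although the run medians were 0.31, -0.03, 0.07 and 0.18. Both measured microglia genes were lower (median -1.04, adjusted p = 0.0011, and adjusted p = 0.20 with an estimated correlation). Cd68 stood at 5.46 ± 2.53 in WT and 3.08 ± 0.221 in S40A and Tyrobp at 4.53 ± 5.46 and 0.452 ± 0.431 (SD, n = 4 each). Both passed adjusted over the list alone, and neither did over all genes. The microglia median was below 0 in 4 of 4 runs (-1.05, -2, -0.37 and -0.75). Tyrobp was highest in replicate 2 of WT, at 12.4 FPKM against 0.591 to 3.08 in the other WT libraries. Without it, its log2 difference went from -1.50 to -0.99 and that of Cd68 from -0.59 to -0.36.

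Among single genes of S40A against WT, Pias4 (chromosome 10, 81153966 to 81167720) had the smallest p, at 16.4 ± 1.67 scaled FPKM in WT and 13.1 ± 0.885 in S40A (SD, n = 4 each; log2 difference -0.30, SE 0.057, adjusted p = 1). Prkacb, a catalytic subunit of protein kinase A, stood at 85.3 ± 5.15 and 119 ± 23.9. Further values were 0.29 for Smim13, Ndfip2 and Endod1, and 0.27 for Ank, a pyrophosphate transporter. They were 0.34 for Oxr1, an oxidation resistance protein, 0.33 for Slitrk2, a synaptic adhesion protein, and -0.47 for Sdf2l1, an endoplasmic reticulum chaperone component. Immediate early factors were higher in 17 of 24 (median 0.07, adjusted p = 0.69) and known CREB targets in 22 of 35 (0.10, 0.38), but their run medians had opposite signs in the library sets. In runs C1, C2, D1 and D2 they were -0.24, -0.92, 1.08 and 0.60 for immediate early factors and -0.12, -0.52, 0.82 and 0.58 for CREB targets. Ribosomal protein genes were lower in 59 of 74 without passing (median -0.11, adjusted p = 0.053).

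S133A, which lacks the phosphorylation site long tied to CREB activation, was compared with GFP and with WT at 8 h. Against GFP, Creb1 rose 71.5-fold (95% interval 24.8 to 206, adjusted p = 0.0066). The other calls by limma were the small RNA entries Snora68 (chromosome 8, 70895759 to 70895856, 98 bp), listed at 0 in 2 of the 16 libraries, and Mir27a (chromosome 8, 84208672 to 84208758, 87 bp), listed at 0 in 14. An unadjusted p under 0.05 was reached by 304 genes, or 754 with the run as a block. Immediate early factors were higher in 17 of 24 (median 0.23, adjusted p = 0.44 by camera) and known CREB targets in 24 of 35 (median 0.23, adjusted p = 0.44), neither passing. Glycolysis genes were lower in 19 of 20 (median -0.20, adjusted p = 0.014), with Pfkp at -0.81 and Eno2 at -0.44, and ribosomal protein genes in 66 of 74 (median -0.41, adjusted p = 7.9e-05), with Rps2 at -0.51. Both were lost with an estimated correlation (adjusted p = 0.98 with an estimated correlation for each), no member passed adjusted over the list alone, and both had an adjusted p of 0.31 without replicate 2 of GFP. Within runs D1 and D2 the medians were -0.17 and -0.02 for glycolysis and -0.02 and -0.03 for ribosomal proteins. Pias4 was at 12.8 ± 0.192 with S133A (n = 2) and 16.2 ± 1.30 with GFP (n = 4), with a log2 difference of -0.40 (adjusted p = 0.49). Gap43 stood at -0.86, Galnt14, a glycosyltransferase, at -0.34, Mark2, a polarity kinase, at -0.25, each with an adjusted p of 1. On the higher side were Arl13b, a GTPase of cilia, at 0.42, Tbc1d7 at 0.34, Ndufaf3, an assembly factor of complex I, at 0.32 and Zfp521 at 0.30, each with an adjusted p of 1. Adck5 was listed at 0 in both S133A libraries and in 1 of 4 GFP libraries. Creb1 itself lost its call without replicate 4 of GFP (adjusted p = 0.052) or without replicate 2 of S133A (0.091), and the count of calls was 9 without replicate 1 of S133A and 6 without replicate 2.

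Against WT, S133A had no list called by camera, fry or an estimated correlation (smallest adjusted p = 0.93 with an estimated correlation, and 0.97 by fry). Fos stood at 532 ± 216 in WT (n = 4) and 525 ± 70.3 in S133A (n = 2), Npas4 at 129 ± 83.9 and 120 ± 48.6, and Bdnf at 9.86 ± 4.88 and 19.4 ± 18.8. Immediate early factors were higher in 19 of 24 (median 0.26, adjusted p = 0.38) and known CREB targets in 25 of 35 (0.13, 0.41). Creb1 differed by a factor of 0.854 (95% interval 0.297 to 2.46), and limma called Snora68 and Mir27a alone. At an unadjusted p under 0.05 there were 180 genes (426 with the run as a block). Single genes were Pias4 at -0.41 (adjusted p = 0.48), Cers2, a ceramide synthase, at -0.38, Mrps9, a mitochondrial ribosome protein, at -0.32, Galnt14 at -0.30, Isy1, a splicing factor, and Pxdn at -0.28 and Lst1 at -0.82. Higher with S133A were Gdf10, a growth factor, at 0.46, Zfp652os at 0.65 and Zfp521 at 0.31, and all but Pias4 had an adjusted p of 1.

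CREB without either site was compared with GFP, WT, S40A and S133A at 8 h. Against GFP, Creb1 rose 84.1-fold (95% interval 29.2 to 242, adjusted p = 0.0067) and limma also called Mir320 (chromosome 14, 70443510 to 70443591, 82 bp), which was listed at 0 in the other 14 libraries of that time. There were 451 genes at an unadjusted p under 0.05 (957 with the run as a block). Pias4 again had the next smallest p (12.3 ± 0.747, n = 2, log2 difference -0.45, adjusted p = 0.24). Next came Pcdh11x, a protocadherin, at 0.55, Zcchc12 at 0.61, Gabrg1, a GABA-A receptor subunit, at 0.50, and BC031181 at 0.33. Lower were Mfap2 at -0.38 and Pinx1, a telomerase inhibitor, at -0.44, each with an adjusted p of 0.97. Ribosomal protein genes were lower in 66 of 74 (median -0.39, adjusted p = 0.00013 by camera) and glycolysis genes in 18 of 20 (median -0.24, adjusted p = 0.017). Neither held (adjusted p = 0.99 with an estimated correlation for each). O-GlcNAc genes were higher in 8 of 9 (median 0.15, adjusted p = 0.031, and adjusted p = 0.99 with an estimated correlation), with Gnpnat1, an enzyme of UDP-GlcNAc synthesis, at 0.25, and lost their call with the run as a block as well (adjusted p = 0.11). No member passed adjusted over the list alone. Without replicate 2 of GFP the 3 adjusted p-values were 0.12, 0.20 and 0.11. Within runs D1 and D2 the medians were -0.04 and 0 for ribosomal proteins, -0.19 and -0.03 for glycolysis, and 0.16 and 0.03 for O-GlcNAc genes. Creb1 lost its call without replicate 4 of GFP (0.055) or replicate 2 of S40A-S133A (0.065). The count of calls was 1 without that GFP library, 10 without replicate 1 of S40A-S133A and 6 without replicate 2. With replicate 2 of S40A left out, Pias4 passed (adjusted p = 0.049, log2 difference -0.46).

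Against WT, cell cycle and astrocyte genes stood higher with S40A-S133A in run D1 and not in run D2. Cell cycle and progenitor genes were higher in 12 of 14 (median 0.26, adjusted p = 0.022 by camera, and adjusted p = 0.97 with an estimated correlation), with Nes at 0.50 and Mki67 at 0.38. Astrocyte and radial glia genes were higher in 9 of 11 (median 0.38, adjusted p = 0.038, and adjusted p = 0.97 with an estimated correlation), with the lipid carrier Fabp7 at 1.06 and the glutamate transporter Slc1a2 at 0.42. Synaptic components were higher in 22 of 29 (median 0.07, adjusted p = 0.032, and adjusted p = 0.97 with an estimated correlation). The astrocyte call was also lost with the run as a block (adjusted p = 0.15). The glial and cycling medians were 0.96 and 0.62 in run D1 but -0.44 and -0.14 in run D2. Without replicate 2 of GFP, which enters the fit through the shared spread and set term, the astrocyte and synaptic calls were lost (adjusted p = 0.067 and 0.062). Limma called Mir320 alone (9 genes without replicate 1 of S40A-S133A and 6 without replicate 2), and 211 genes had an unadjusted p under 0.05 (468 with the run as a block). Pias4 was at -0.46 (adjusted p = 0.27), Gal, which encodes the neuropeptide galanin, at -1.09, Nme4, a mitochondrial nucleoside diphosphate kinase, at -0.57, and Casp6, a caspase, at -0.39. Higher were Zfp652os at 0.77, Surf1, an assembly factor of complex IV, at 0.51, Krcc1 at 0.49, Pxmp2, a peroxisomal membrane protein, at 0.48, Pcdh11x at 0.47 and Mmab at 0.39, and all but Pias4 had an adjusted p of 1. Creb1 differed by a factor of 1.01 (95% interval 0.349 to 2.89).

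Against S40A, S40A-S133A had lower oxidative phosphorylation genes, 29 of 32 (median -0.17, adjusted p = 1.7e-07 by camera, and adjusted p = 0.70 with an estimated correlation), with Uqcrc1 at -0.29 and Uqcrfs1 at -0.22. Cell cycle genes were higher, 12 of 14 (median 0.35, adjusted p = 0.00042, and adjusted p = 0.70 with an estimated correlation), with Top2a at 0.67 and Nes at 0.64. Both microglia genes were higher (median 0.84, adjusted p = 0.029, and adjusted p = 0.70 with an estimated correlation), Tyrobp by 1.16. Ribosomal protein genes were higher in 65 of 74 (median 0.22, adjusted p = 0.039, and adjusted p = 0.91 with an estimated correlation), although their medians within runs D1 and D2 were -0.01 and -0.12 and the call was lost without replicate 2 of GFP (adjusted p = 0.63). The cell cycle medians were 0.50 in run D1 and -0.07 in run D2. With the run as a block the microglia and ribosomal calls were lost (adjusted p = 0.062 for each). Limma called Mir320 alone (9 genes without replicate 1 of S40A-S133A and 6 without replicate 2), with 241 genes at an unadjusted p under 0.05 (430 with the run as a block). Pxmp2 was at 0.793 ± 0.150 in S40A (n = 4) and 2.07 ± 0.0752 in S40A-S133A (n = 2), with a log2 difference of 0.74 and an adjusted p of 0.78. Sdf2l1, at 0.66, was the 1 gene of the unfolded protein list to pass adjusted over the list alone. Zic5, a transcription factor, was at 0.70, Fam229b at 0.68, Egfr, the epidermal growth factor receptor, at 0.57 and Ppil2 at 0.35. Gal was at -1.04, Entpd3, an ectonucleotidase, at -0.44, Mrps34 at -0.39 and Lysmd2 at -0.31, and each of these had an adjusted p of 1. Creb1 differed by a factor of 1.01 (95% interval 0.353 to 2.92).

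S40A-S133A differed from S133A only in the S40 site (n = 2 each). Limma called Mir320, Snora68 and Mir27a. There were 44 genes at an unadjusted p under 0.05, where chance gives 605. A count so far below chance cannot show that effects are absent. Calls rose with 1 library left in a group. By gene list, 0 lists were called by camera or with an estimated correlation (smallest adjusted p = 0.96 with an estimated correlation). Creb1 differed by a factor of 1.18 (95% interval 0.37 to 3.75). Fbxl15 stood at -0.37, Il11ra1, an interleukin receptor chain, at -0.37, Nudt14 at -0.34, Popdc3 at -0.31, Mmadhc at -0.22 and Xpnpep1 at -0.17. Higher were Zcrb1 at 0.27, Xndc1 at 0.31 and Moap1, a modulator of apoptosis, at 0.60, with an adjusted p of 1 each. Rrp8, a methyltransferase of ribosomal RNA, was listed at 0 in 1 of the 2 S40A-S133A libraries. With replicate 1 of S40A-S133A left out the lone remaining library was the one at 0, and Rrp8 was then called.

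The interplay of both sites was tested as the S40A effect in the absence of S133 (S40A-S133A minus S133A) minus that in its presence (S40A minus WT). Limma again called Mir320, Snora68 and Mir27a, and 83 genes had an unadjusted p under 0.05 (159 with the run as a block). Calls rose with 1 library left in a group. For Creb1 the interaction was 0.25 (SE 0.94, adjusted p = 1). Synaptic components had a negative interaction in 27 of 29 (median -0.17, adjusted p = 0.00034 by camera, and adjusted p = 0.48 with an estimated correlation), with Grin1 at -0.40 and Snap25 at -0.20. Oxidative phosphorylation genes had one in 30 of 32 (median -0.12, adjusted p = 8.4e-05, or 0.91 with an estimated correlation), with Uqcrfs1 at -0.22. Both microglia genes had a positive interaction (median 1.14, adjusted p = 0.0082, or 0.48 with an estimated correlation). S40A minus WT alone holds runs C1 and C2, with medians of -1.05 and -2 (-0.37 and -0.75 in D1 and D2). No member passed adjusted over the list alone. Known CREB targets were negative in 27 of 35 (median -0.15, adjusted p = 0.19). Named genes were Gdf10 at -0.54, Rnf113a1, a ring finger protein, at -0.51, Slitrk2 at -0.46, and Hcfc1r1 at -0.31. Positive values were Sdf2l1 at 0.59, Tmem192, a lysosomal membrane protein, at 0.52, Pole3, a small subunit of DNA polymerase epsilon, at 0.44, Smn1, the survival of motor neuron gene, at 0.38, Cers2 at 0.33 and Frg1 at 0.31, each with an adjusted p of 1.

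**Figure D4:**
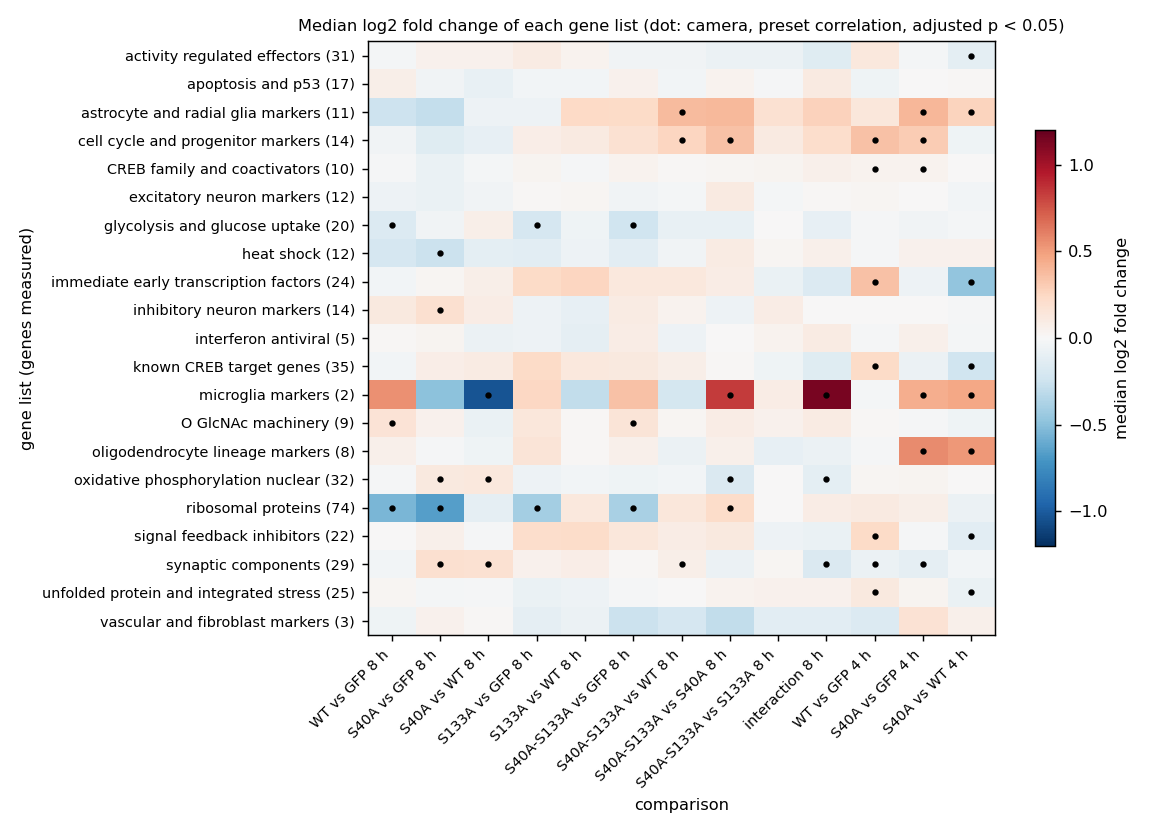
Median log2 difference of each gene list (rows, with the number of genes measured) in each comparison (columns), as colour, with a dot where camera at the preset correlation gave an adjusted p under 0.05. In S40A against WT at 8 h the synaptic and oxidative phosphorylation medians were 0.18 and 0.13, and in the interaction -0.17 and -0.12.

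After 4 h of expression, immediate early factors, CREB targets and feedback inhibitors stood higher with WT than with GFP. All 24 immediate early transcription factors were higher (median 0.35, adjusted p = 0.004 by camera, and adjusted p = 0.87 with an estimated correlation). Klf10 stood at 10.0 ± 0.718 in GFP and 13.4 ± 2.12 in WT, Csrnp1 at 6.84 ± 2.58 and 12.7 ± 4.89, and Srf at 45.7 ± 18.7 and 53.1 ± 11.4 scaled FPKM (SD, n = 2 each). Known CREB targets were higher in 29 of 35 (median 0.23, adjusted p = 0.033, and adjusted p = 0.87 with an estimated correlation), with Cartpt, a neuropeptide, at 0.44 and the GTPase Gem at 0.31. Signal feedback inhibitors were higher in 18 of 22 (median 0.23, adjusted p = 0.01, and adjusted p = 0.87 with an estimated correlation), with the phosphatase Dusp5 at 0.44. Activity-regulated effectors were higher in 23 of 31 without passing (median 0.13, adjusted p = 0.067, run medians -0.08 in A and 0.29 in B). Cell cycle genes were higher in 14 of 14 (median 0.35, adjusted p = 3.8e-05, and adjusted p = 0.87 with an estimated correlation). So were unfolded protein and integrated stress genes in 23 of 25 (median 0.12, adjusted p = 3.8e-05, and adjusted p = 0.59 with an estimated correlation), with Ddit4 at 0.24 and Atf5 at 0.23. Synaptic components were lower in 22 of 29 (median -0.07, adjusted p = 0.047, and adjusted p = 0.87 with an estimated correlation). The CREB family list was called through Creb1 alone (median 0.04, adjusted p = 0.016, and adjusted p = 0.59 with an estimated correlation), and it was not called with the replicate number as a block (0.17).

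Creb1 rose 17.0-fold at 4 h in WT (95% interval 12.2 to 23.6, adjusted p = 0.014) and 17.2-fold in S40A (12.3 to 23.9, adjusted p = 0.016), and S40A and WT differed in it by a factor of 1.01 (0.727 to 1.41). Limma called 12 genes for WT against GFP (7 higher, 5 lower), of which the other 11 were small RNA entries such as Snord92, Mir7048 and Mir92b that were listed at 0 in some libraries. At an unadjusted p under 0.05 there were 38 genes, or 263 with the replicate number as a block. The count of calls was 27 without either replicate of GFP, and 29 and 20 without replicates 1 and 2 of WT. The calls of Creb1 depended on single libraries with n = 2 per group, since that in WT was lost without either replicate of WT (adjusted p = 0.095 and 0.14) or of S40A (0.078 and 0.084). That in S40A was lost without replicate 1 of GFP (0.055), either replicate of WT (0.090 and 0.092) or either of S40A (0.075 and 0.072). Within runs the immediate early median of WT minus GFP was 0.45 in run A and 0.20 in run B, that of the cell cycle genes 0.99 and -0.10, and that of synaptic components -0.21 and 0.07.

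In S40A against GFP at 4 h, oligodendrocyte lineage markers stood higher in both runs. They were higher in 7 of 8 (median 0.57, adjusted p = 2.7e-10 by camera, and adjusted p = 0.13 with an estimated correlation), with the transcription factor Olig1 at 24.8 ± 1.14 in GFP and 40.9 ± 1.09 in S40A and the growth factor receptor Pdgfra at 3.62 ± 0.934 and 7.51 ± 0.542 scaled FPKM (SD, n = 2 each). Olig1 and Pdgfra passed adjusted over the list alone, and 0 of the 8 passed over all genes. Astrocyte and radial glia genes were higher in 11 of 11 (median 0.40, adjusted p = 0.0006), with Gfap at 0.73 and Hopx at 0.58, and cell cycle genes in 13 of 14 (median 0.30, adjusted p = 0.004). Neither held (adjusted p = 0.88 with an estimated correlation for each). Synaptic components were lower in 24 of 29 (median -0.11, adjusted p = 0.012, and adjusted p = 0.92 with an estimated correlation). The microglia list was called on Tyrobp at 0.89 with Cd68 at -0.01 (median 0.44, adjusted p = 0.033, and adjusted p = 0.56 with an estimated correlation), and the CREB family list on Creb1 (adjusted p = 0.012, and adjusted p = 0.55 with an estimated correlation). Neither of the last 2 lists was called with the replicate number as a block (0.25 and 0.19). Limma called 11 genes (7 higher, 4 lower), Creb1 and 10 small RNA entries, with 59 at an unadjusted p under 0.05, or 362 with the replicate number as a block. The count of calls was 22 and 29 without replicates 1 and 2 of GFP and 28 and 34 without those of S40A. Oligodendrocyte medians were above 0 in both runs, 0.34 in A and 0.68 in B, while those of astrocyte genes were of opposite sign, 0.95 and -0.25, as were those of cell cycle genes, 0.74 and -0.13, and of synaptic components, -0.28 and 0.08.

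In S40A against WT at 4 h the activity genes stood lower. Known CREB targets were lower in 33 of 35 (median -0.24, adjusted p = 0.00053 by camera, and adjusted p = 0.92 with an estimated correlation), with the secreted neuropeptide precursor Vgf at -0.32. Immediate early factors were lower in 21 of 24 (median -0.47, adjusted p = 0.0057, and adjusted p = 0.92 with an estimated correlation), with Egr1 at 281 ± 142 in WT and 214 ± 176 in S40A (SD, n = 2 each), Klf4 at -0.77 and Srf at -0.36. So were activity-regulated effectors in 28 of 31 (median -0.12, adjusted p = 0.0057), signal feedback inhibitors in 20 of 22 (median -0.13, adjusted p = 0.01) and unfolded protein genes in 21 of 25 (median -0.08, adjusted p = 0.0057). Of these none held (adjusted p = 0.85, 0.92 and 0.74 with an estimated correlation). Oligodendrocyte markers were higher in 7 of 8 (median 0.52, adjusted p = 2e-11, and adjusted p = 0.11 with an estimated correlation), with Sox10 at 1.31 ± 0.458 and 2.66 ± 0.764 and Cnp at 4.41 ± 0.906 and 7.56 ± 2.39, and astrocyte genes in 9 of 11 (median 0.27, adjusted p = 0.01, and adjusted p = 0.92 with an estimated correlation). The microglia pair had a median of 0.46 (adjusted p = 0.01, and adjusted p = 0.65 with an estimated correlation). No member passed adjusted over the list alone. Limma called 11 genes (6 higher, 5 lower), all small RNA entries, or 7 with the replicate number as a block, and 38 had an unadjusted p under 0.05, or 186 with it. The block also ended the astrocyte and microglia calls (0.064 and 0.19). Within runs the immediate early median was -0.80 in A and -0.11 in B and that of CREB targets -0.26 and -0.12. The count of calls was 0 and 7 without replicates 1 and 2 of GFP, 24 and 22 without those of WT, and 28 and 31 without those of S40A. Leaving out replicate 1 of S40A turned Egr1 to 0.36 and Klf4 to 0.44.

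Whether effects differed between 4 and 8 h was tested in the joint fit. For S40A against WT, known CREB targets shifted upward from 4 to 8 h in 32 of 35 (median 0.41, adjusted p = 0.002 by camera, and adjusted p = 0.84 with an estimated correlation), with Cartpt at 2.01 (SE 0.83). So did immediate early factors in 22 of 24 (median 0.46, adjusted p = 0.024) and effectors in 24 of 31 (median 0.22, adjusted p = 0.045). Neither held (adjusted p = 0.84 with an estimated correlation for each). At 8 h the medians of these 3 lists lay below 0 in the runs of the earlier set and above 0 in those of the later one. In runs C1, C2, D1 and D2 the 8 h medians were -0.12, -0.52, 0.82 and 0.58 for CREB targets, against -0.26 and -0.12 in runs A and B at 4 h. They were -0.24, -0.92, 1.08 and 0.60 for immediate early factors, against -0.80 and -0.11, and -0.05, -0.35, 0.30 and 0.46 for effectors, against -0.15 and -0.09. An upward shift was also found for synaptic components in 27 of 29 (median 0.21, adjusted p = 4.5e-05, and adjusted p = 0.78 with an estimated correlation) and oxidative phosphorylation genes in 31 of 32 (median 0.12, adjusted p = 0.00041, and adjusted p = 0.84 with an estimated correlation). Oligodendrocyte markers shifted downward in 8 of 8 (median -0.45, adjusted p = 0.00044, and adjusted p = 0.53 with an estimated correlation) and microglia genes by a median of -1.5 (adjusted p = 4.5e-05, and adjusted p = 0.071 with an estimated correlation). Tyrobp, at -2.46, passed adjusted over the list alone. For WT against GFP the shift was downward for immediate early factors in 24 of 24 (median -0.39, adjusted p = 0.014), cell cycle genes in 14 of 14 (-0.43, 0.00023), astrocyte genes in 11 of 11 (-0.33, 0.022), unfolded protein genes in 20 of 25 (-0.14, 0.014) and ribosomal protein genes in 69 of 74 (-0.72, 4.1e-09). None held (adjusted p = 0.81, 0.76, 0.80, 0.76 and 0.76 with an estimated correlation). For S40A against GFP, synaptic components shifted upward in 26 of 29 (median 0.28, adjusted p = 1.5e-05) and oxidative phosphorylation genes in 24 of 32 (0.09, 0.026), and neither held (adjusted p = 0.74 and 0.88 with an estimated correlation). Astrocyte genes (-0.56, 0.0025), cell cycle genes (-0.46, 0.0029), the microglia pair (-0.93, 0.021), oligodendrocyte markers (-0.62, 0.001) and ribosomal protein genes (-0.74, 4.6e-07) shifted downward. Again none held (adjusted p = 0.74 with an estimated correlation for astrocyte, cell cycle and ribosomal genes and 0.60 for microglia and oligodendrocyte). Without replicate 2 of GFP at 8 h the ribosomal calls were lost for WT and S40A against GFP (adjusted p = 0.086 and 0.11), as was that of effectors for S40A against WT (0.057).

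By single genes, the fold of Creb1 over GFP differed between the times by 2.30 on the log2 scale for WT and 2.27 for S40A (SE 0.83, adjusted p = 1 for both). Gap43 had a shift of -0.93 for WT, Tstd1 1.06, and Gal 1.07 and 1.08 for WT and S40A. Pcdh11x had a shift of 0.74, Gabrg1 0.59, Pxmp2 -0.83, Sun2, a nuclear envelope protein, -0.58, Carf 0.55 and 0.63, and Mrpl46 -0.33 for WT and 0.34 for S40A against WT. In S40A against WT, Bcl2l2, an apoptosis inhibitor, had a shift of 0.60, Tmod1, an actin capping protein, 0.93 and Ttc7b 0.49. All of these had an adjusted p of 1. Limma called 2, 1 and 3 genes in the 3 differences, with 68, 140 and 107 at an unadjusted p under 0.05, and each call was a small RNA entry listed at 0 in all 16 libraries at 8 h. Leaving out a 4 h library raised these counts, to 6 and 5 without replicates 1 and 2 of GFP and 7 and 6 without those of WT for WT against GFP. For S40A against GFP it gave 5 and 4 without those of GFP and 10 and 11 without those of S40A, and leaving out either replicate of S40A-S133A gave 2. For S40A against WT it gave 8 and 7 without those of WT and 13 and 14 without those of S40A.

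WT and S40A were compared for the likeness of their changes against the same GFP libraries. Across 11177 genes, which are not independent replicates, the 8 h changes had r = 0.60 and rho = 0.42, against a simulated r of 0.50 (0.47 to 0.54 over 100 simulations) for unchanged groups sharing those controls. The covariance was 0.0252 against 0.0217 simulated, a difference of 0.00348, and 64.9% of genes had the same sign against 66.7% simulated. With the GFP libraries split between both comparisons r was -0.18 (-0.27 to -0.06 over 4 splits). Within each set the split gave the comparisons GFP libraries of different runs, while WT and S40A covered both runs. Run differences then enter with opposite signs and push r below 0, so this value cannot tell whether the changes are alike. The only shared call was Creb1, which both viruses carry. For S40A and S133A against the same WT libraries r was 0.30 and rho 0.26, against a simulated 0.39 (0.33 to 0.45), the covariance was 0.0115 against 0.0214, 60.4% had the same sign against 62.6%, and 0 calls were shared. In comparisons that share no library within the later set, the S133 effect with S40 present and absent correlated across genes with r = 0.36 (rho 0.30), and the S40 effect with S133 present and absent with r = -0.03 (rho 0.01). Both lay within what reassigning the 4 virus labels within runs gave (median r 0, from -0.62 to 0.61 in 95% of 100 draws). For the S133 effect r was 0.55 within run D1 and 0.20 within D2, but -0.09 and -0.03 when the effects came from different runs. In run D1, S133A and S40A-S133A were each other's most alike library (r = 0.993) and stood apart from the rest of that run, at 7.3 and 5.5 on the first principal component against 18.1 to 19.4, and at -7.3 and -9.5 on the second against 4.3 to 19.2. In run D2 they were at 19.2 and 19.9 on the first, where the others were at 19.9 to 20.7.

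Activity genes followed the run in the later 8 h set. There, levels of Fos, Npas4, Bdnf, Nr4a1, Arc, Egr1, Nr4a2 and Crem were higher in run D2 than in run D1 in 5 of 5 groups, GFP included. The median log2 differences were 0.52, 1.04, 2.07, 1.27, 1.12, 0.70, 1.77 and 1.39. The list medians were 1.02 for immediate early factors, 0.98 for effectors, 0.94 for known CREB targets and 0.73 for signal feedback inhibitors. The median run difference of Creb1 was 1.69, with 4 of 5 groups higher in D2. The earlier set had no common direction between its runs. Its immediate early medians, as log2 deviations from each gene's mean at 8 h, were 0.43 in run C1 and 0.09 in run C2 for GFP, 0.46 and 0.62 for WT, and 0.13 and -0.30 for S40A.

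**Figure D5:**
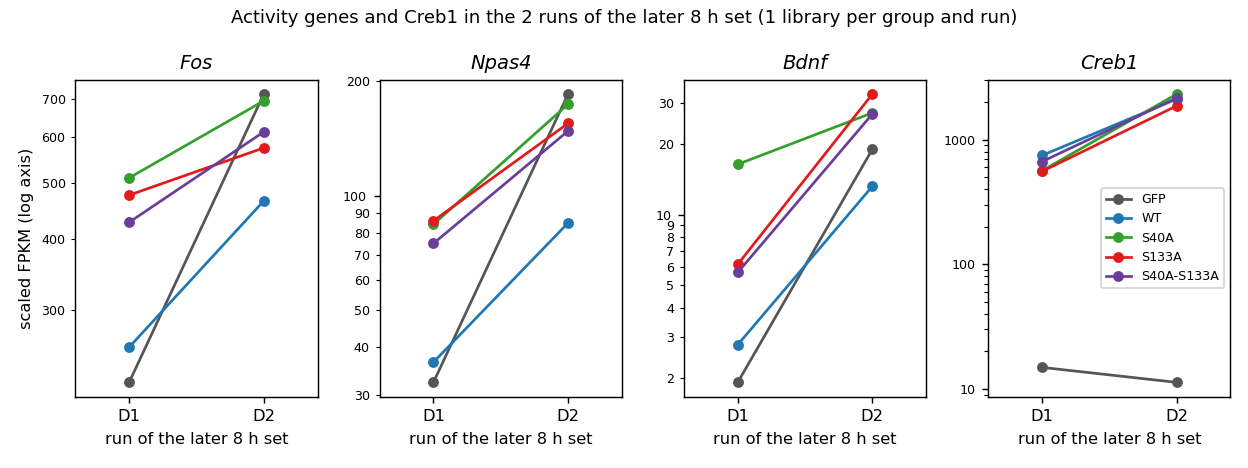
Scaled FPKM (log axes) of Fos, Npas4, Bdnf and Creb1 in runs D1 and D2 of the later 8 h set, with 1 point per library and a line joining the libraries of a group. Fos, Npas4 and Bdnf are higher in run D2 in 5 of 5 groups, and Creb1 is so in the 4 CREB groups and not in GFP.

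A few further lists were not called in any comparison, and their WT against GFP values at 8 h stand for them. Excitatory neuron markers divided 5 higher to 7 lower (median -0.06, adjusted p = 0.77), apoptosis and p53 genes 11 to 6 (0.07, 0.62), the 5 measured interferon genes 3 to 2 (0.01, 0.74) and the 3 measured vascular genes 1 to 2 (-0.05, 0.74). Fry's directional test called 0 lists in any of the comparisons, and its mixed test called the CREB family list in each comparison with GFP at 4 and 8 h. It also called the oligodendrocyte list in S40A against GFP at 4 h (adjusted p = 0.029). Among all lists and comparisons, the median, mean and test differed in sign only for lists that were not called.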

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

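The tests of library structure, of Pias4 and of Gap43 in this part were chosen after their results were seen, while the rules that single out libraries and genes were fixed before.

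Replicate 2 of GFP at 8 h stood far from the other GFP libraries in the share of low values well below the value of 1 read, 6.74% against 0 to 0.324% (gap of 0.952 of the group's range), and its ribosomal protein RNAs had a median 1.89 above theirs on the log2 scale. Greater depth was argued against, since the 8 h library with the most estimated reads deviated by 0.18 in these genes and replicate 2 by 2.23, and so were cells of other types, whose 5 marker lists had medians from -0.41 to 0.22 in it. Reads shared with pseudogene copies and counted differently in that library remain a candidate explanation, because among genes other than ribosomal proteins 29.2% of those with a named pseudogene (56 of 192) were higher there by over 1, against 2.25% of the others (245 of 10888; odds ratio 17.9, 95% interval 12.5 to 25.3, Fisher's exact test p = 6.6e-43, with genes taken as independent). Replicate 1 at 4 h, also rich in values under 1 read, exceeded replicate 2 by a median 1.83 in ribosomal proteins. Other genes with a pseudogene gave 0.53 and the rest 0. Which libraries show the true levels was not tested. The groups give no biological explanation for 1 library, so no other was tested. Such a difference in counting is not recorded in the sources used here.

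Pias4, a SUMO ligase, was lower in the 8 libraries with a mutant CREB at 8 h (11.8 to 13.6 scaled FPKM) than in the 8 with WT CREB or GFP (14.7 to 17.8), a pattern seen first and then tested by pooling the mutants. Sets or runs as the whole cause were argued against, since each run holds both kinds of library. A run term left Pias4 at -0.35 (SE 0.043, adjusted p = 0.023), which it cannot move, as both runs of a set hold equal mutant shares. Chance stays open, because the grouping was chosen for this gene; over 5 forms of the test 1 to 7 of 100 groupings gave as much, and with a run term, 1 of 100 groupings, the real one, called as many long named genes (18, highest other 16), and 7 of 100 had as many at an unadjusted p under 0.05 (1530, highest other 2700). Of 3 forms of the pooled contrast, the set term called 1 gene (Pias4 at -0.35, SE 0.044, adjusted p = 0.013) and the run term 36, or 18 among long named genes, including Cacna2d1 (0.33), Pcdh11x (0.40), Gnai1 (0.22) and Prkacb (0.38) higher and Shkbp1 (-0.27), Pinx1 (-0.31) and Polr1c (-0.22) lower. In the earlier set Xist, a gene of cell sex, was 38 and 24 in S40A, 0.085 and 70 in WT and 0.11 and 27 in GFP. The called long named genes on chromosome X, Pcdh11x, Cnksr2 (0.38), Atp6ap1 (0.20) and Ptchd1 (0.38), were all higher with mutant CREB. A part of cell sex in these calls was not tested, and the fits hold no term for it. A hypothesis is that loss of either site may lower Pias4, but at 4 h S40A and WT differed by -0.01 (SE 0.38), and the finding rests on the libraries that raised it.

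Gap43, a growth cone protein, was lower in the 12 libraries with a CREB virus than in the 4 GFP libraries at 8 h. A lower share of neurons was argued against, since the lowest of the 4 medians of excitatory neuron markers against GFP was -0.08 where Gap43 of WT against GFP was -1.16. Chance among all genes was not excluded, as 5 of 100 choices of 4 libraries, 1 from each run as in GFP and the real one included, separated as many long named genes (15, highest other 53), and so did 16 of 100 that took 2 libraries per set whatever their run (highest other 105). The amount of virus-derived Creb1 RNA may account for the pattern, since Gap43 fell with Creb1 over the 12 CREB libraries with run means removed (r = -0.65, permutation p = 0.035, rho = -0.73, p = 0.011, r without the 2 farthest libraries -0.53) and with set means removed (r = -0.70, p = 0.0016, rho = -0.76, p = 0.00089, r without them -0.61), 2 relations with adjusted p-values of 0.035 and 0.0032. From run D1 to D2 Gap43 went from 654 to 895 in GFP and by -0.24 to -0.37 on the log2 scale in the 4 CREB groups, and without replicate 2 of GFP its WT against GFP value was -1.07.

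The 35 splits of the 8 libraries of each pair of groups, the real one included, did not exclude chance for the counts at 8 h that could be tested. For WT against GFP, 2 splits (the real one is counted in each number) called as many genes as it did (1, highest other 2) and 27 had as many at an unadjusted p under 0.05 (130, highest other 2370). For S40A against GFP the numbers were 6 (1, highest other 98) and 10 (717, highest other 2209), and for S40A against WT 10 at an unadjusted p under 0.05 (514, highest other 2318). Its count of called genes was 0, which all 35 splits reach by construction (highest other 2) and which tests nothing. Splits with several times the real number point to a structure of the samples. The split by runs (replicates 1 and 3 against 2 and 4) gave 1480, 566 and 1181, under the highest of each pair. The splits did not keep the runs together, and with the run as a block the unadjusted counts were 295, 1273 and 897.

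Of 216 tests for a single library that stands apart, 13 found one against 11 that chance gives, with 7 in GFP at 8 h. One of these is the share of low values given above, and the others are named genes. In GFP at 8 h, replicate 1 stood apart in Adck5 (0 against 4.87 to 6.44 scaled FPKM, 0.882 of the range), BC031181 (58.4 against 53.1 to 53.9, 0.831) and Il11ra1 (0.753 against 1.56 to 1.76, 0.832), and replicate 2 in Nudt14 (3.88 against 5.65 to 6.05, 0.838), Sdf2l1 (1.96 against 3.06 to 3.24, 0.875) and Vkorc1 (7.70 against 10.3 to 10.4, 0.953). In WT at 8 h, replicate 2 stood apart in Mfap2 (19.5 against 23.2 to 23.7, 0.884) and replicate 4 in Prkacb (77.6 against 86.6 to 88.6, 0.831). In S40A at 8 h, replicate 4 stood apart in Adck5 (5.79, the others listed at 0, a gap of 1 of the range), replicate 1 in Gdf10 (10.9 against 9.24 to 9.49, 0.840) and Pias4 (11.8 against 13.4 to 13.6, 0.911), and replicate 3 in Nudt14 (5.53 against 4.78 to 4.89, 0.845).

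Small RNA entries were called by the test of a difference between effects. The interaction of the substitutions was called for Mir320 (adjusted p = 3.98e-06), Snora68 (0.00579) and Mir27a (1.81e-10), but the joint fit of 22 libraries called 0 genes for it. A difference between the 4 and 8 h effects was called in WT against GFP for Mir92b (1.98e-10) and Mir6399 (1.98e-10), in S40A against GFP for Snord73a (3.3e-12), and in S40A against WT for Snord73a (3.3e-12), Mir92b (4.48e-10) and Mir6399 (1.98e-10). Mir320 and Mir27a are listed at 0 in 14 of the 16 libraries at 8 h and Snora68 in 2. The entries of the time differences are listed at 0 in all 16 libraries at 8 h and in 2 or 4 of the 6 at 4 h. An exact 0 can be a failed estimate, and libraries at 0 add no spread, so these p-values are not read as differences between groups and no fold is given.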

How the results depend on the processing

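The tests limited to long named genes, the list tests without replicate 2 of GFP at 8 h, and the run block combined with either of these or with the list tests were chosen after the results were seen. The rest were planned. Apart from the leave-one-out fits, 3859 comparisons of a named gene's value with its alternative kept direction and side of the threshold, 8 lost a call and 19 changed sign. In the leave-one-out fits these numbers were 3657, 13 and 60, and 4 gained a call. Of the list calls under an alternative, 150 were kept, 163 lost and 3 changed direction. Counts of called genes stayed within 1.5 times in 156 cases and moved in 54, in the leave-one-out fits in 197 and 47, and counts of called lists in 49 and 35. The prior without a trend, the robust prior, a pseudocount of 0.1 and the fit without a set term moved no count by over 1.5 times. Depth limits the genes near 1 FPKM and the small RNA entries of 55 to 104 bp, where an exact 0 can be a failed estimate. Where no reason is given, the cause was not tested.

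With a correlation estimated per list, and with fry, the count of called lists became 0 in each comparison where camera had called any. The camera counts were 3, 5 and 3 for WT against GFP, S40A against GFP and S40A against WT at 8 h, 2 for S133A against GFP, 3, 3 and 4 for S40A-S133A against GFP, WT and S40A, 3 for the interaction, 7, 6 and 8 at 4 h, and 5, 7 and 7 for the differences between times. Without replicate 2 of GFP at 8 h, in WT against GFP the adjusted p of the glycolysis list went from 0.041 to 0.55 and that of the ribosomal list from 8.5e-12 to 0.45, both with a change of direction, and the list counts for S133A and S40A-S133A against GFP went from 2 and 3 to 0 and 0. The gene counts without it were 1, 1 and 0 for WT against GFP, S40A against GFP and S40A against WT, with 84, 807 and 735 genes at an unadjusted p under 0.05. Split controls took the correlation of the WT and S40A changes from 0.60 to -0.18, but there run differences enter the comparisons with opposite signs and push it below 0. Without further scaling, the list count of WT against GFP between times went from 5 to 8 and the mean Creb1 of WT at 4 h from 249 to 237. Quantile normalization turned Creb1 from -0.01 to 0.14 in S40A against WT, -0.23 to 0.07 in S133A against WT, 0.02 to -0.09 and 0.24 to -0.02 in S40A-S133A against S40A and S133A, 0.25 to -0.16 in the interaction and -0.03 to 0.07 in S40A against WT between times, none of which was a called difference.

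The earlier set alone gave 13, 14 and 10 called genes for WT against GFP, S40A against GFP and S40A against WT in place of 1, 1 and 0, and turned Creb1 of S40A against WT to 0.11. The later set alone gave 2, 3 and 1 for those, 5, 3, 4 and 5 for S40A-S133A against GFP, WT, S40A and S133A, and 6 for the interaction. It also ended the Creb1 calls against GFP (adjusted p = 1, 1 and 1 for WT, S40A and S133A, and 0.57 for S40A-S133A), although the log2 differences stayed at 6.49, 6.35, 6.18 and 6.42 (SE 0.99 each, against 6.39, 6.37, 6.16 and 6.39 with SE 0.54, 0.54, 0.70 and 0.70 in both sets). That fit has 5 residual degrees of freedom and no term for the runs, between which Creb1 differed 3.34-fold. It turned Pgk1, Pgam1 and Ogt of WT against GFP to 0.04, 0.09 and -0.01, and Creb1 of S40A-S133A against WT to -0.07. A single set holds fewer samples. The joint fit of 22 libraries gave 1 for S133A against WT, 1, 0, 0 and 0 for S40A-S133A against GFP, WT, S40A and S133A, 0 for the interaction, and 2, 1 and 3 at 4 h, where Creb1 had adjusted p-values of 0.092 and 0.13. Limited to long named genes, where small RNA entries are left out by construction, the counts were 1 and 0 for S133A against GFP and WT, 1, 0, 0 and 0 for S40A-S133A, 0 for the interaction, 0, 0 and 0 at 4 h, where Creb1 had adjusted p-values of 0.054 and 0.053, and 0, 0 and 0 between times. With a run block as well, the 4 h counts were 2, 1 and 1, and those at 8 h were 1, 0, 1, 0, 0, 0 and 0 in the same order. The run block alone took the WT against GFP list count from 3 to 1, and it ended 6 of 26 list calls at 8 h. These were the O-GlcNAc and glycolysis lists of WT against GFP (adjusted p = 0.084 and 0.10), the O-GlcNAc list of S40A-S133A against GFP (0.11), the astrocyte list of S40A-S133A against WT (0.15), and the microglia and ribosomal lists of S40A-S133A against S40A (0.062 and 0.062). Without replicate 2 of GFP as well, the block turned Gapdh and Pgam1 to 0.06 and 0.06. A minimum mean of 5 FPKM gave 1 gene in place of 2 for WT against GFP between times. Without a filter the counts were 2, 2 and 5 for S40A-S133A against WT, S40A and S133A, 5 for the interaction, 4 for S40A against WT at 4 h, and 3 and 5 for S40A against GFP and WT between times.

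At 8 h, 26 pairs with the same replicate number had a median r of 0.17 (-0.10 to 0.79) and 74 with other numbers -0.11 (-0.79 to 0.54). The numbers start again for S133A and S40A-S133A, so some of the 26 cross runs. The 20 pairs of the same run in the later set had a median r of 0.425 (0.06 to 0.79). With that replicate block, counts went from 1 to 2 for S40A-S133A against WT and against S40A, list counts from 3 to 1 for WT against GFP, 0 to 2 for S133A against WT and 3 to 5 for S40A-S133A against GFP, and the ribosomal list of S40A-S133A against S40A changed direction (adjusted p from 0.039 to 0.019). Galnt14 turned to 0.09 and 0.12 in S133A against GFP and WT, Pfkl to 0.05 in S133A and 0.05 in S40A-S133A against GFP, Creb1 to 0.05 in S133A against WT, and Rpl38 from 1.28 to -0.15 in S40A-S133A against S40A. At 4 h, where number and run coincide, the replicate block gave 10 and 8 genes for WT and S40A against GFP and 7 for S40A against WT, and apart from the lists named with the 4 h results it changed no other list call.

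Leaving out 1 library at a time, where a group of 2 then rests on a lone library assumed to vary like the others, gave 1 to 1, 1 to 1 and 0 to 0 genes for WT against GFP, S40A against GFP and S40A against WT at 8 h. The ranges were 2 to 9 for S133A against GFP and 2 to 8 against WT, highest without replicate 1 of S133A, and 1 to 10, 1 to 9, 1 to 9 and 3 to 11 for S40A-S133A against GFP, WT, S40A and S133A and 3 to 11 for the interaction, highest without replicate 1 of S40A-S133A. At 4 h they were 12 to 29 for WT against GFP, highest without replicate 1 of WT, and 15 to 34 and 0 to 31 for S40A against GFP and WT, highest without replicate 2 of S40A, the 0 being without replicate 1 of GFP. Between times they were 2 to 7, 1 to 11 and 3 to 14. Creb1 of WT at 4 h ranged from 248 to 250. Named genes whose sign changed at 4 h included, in WT against GFP, Atf2 (-0.22 to 0.05), Crebbp (-0.05 to 0.34), Ep300 (-0.03 to 0.36), Srf (-0.16 to 0.68) and Tob2 (-0.14 to 0.86). In S40A against GFP they included Cd68 (-0.23 to 0.22), Crebbp (-0.07 to 0.32), Crtc1 (-0.30 to 0.11) and Crtc3 (-0.03 to 0.41). In S40A against WT they included Cartpt (-0.52 to 0.04), Cd68 (-0.24 to 0.15), Cpne7 (-0.48 to 0.02), Egr1 (-1.54 to 0.36), Gem (-0.49 to 0.01), Gja1 (-0.05 to 0.51), Klf10 (-0.31 to 0.05), Klf4 (-1.97 to 0.44), Manf (-0.26 to 0.03), Ppp1r15a (-0.49 to 0.08), Spred2 (-0.23 to 0.01), Spry4 (-0.80 to 0.18) and Creb1 (-0.08 to 0.11). At 8 h they included Gapdh (-2.17 to 0.06), Pgam1 (-1.75 to 0.09) and Pgm3 (-0.01 to 0.27) in WT against GFP and Gria2 (-0.03 to 0.64) in S40A-S133A against WT. Creb1 ranged from -1.10 to 0.64 in S133A against WT, -0.38 to 0.39 in S40A against WT, -0.39 to 0.37 in that difference between times, -0.64 to 1.11, -0.83 to 0.87 and -0.84 to 0.85 in S40A-S133A against S133A, S40A and WT, and -0.62 to 1.12 in the interaction. Ddit3, listed at 0 in most libraries, gained a call at 4 h without replicate 2 of WT (adjusted p = 0.0042 and 0.0036 for WT against GFP and S40A against WT).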

Other observations

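The values in this part were looked at after the main results were seen, and no tests were made of them.

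Genes of cell sex differed between libraries of the same group. Xist, the RNA that coats an inactive X chromosome, exceeded 10 FPKM in 4 libraries, all of the earlier 8 h set, namely replicate 2 of GFP (27), replicate 2 of WT (70) and replicates 1 and 2 of S40A (38 and 24). Xist was under 1 FPKM in the other 18, of which 17 had the Y-linked gene Eif2s3y above 5. Replicate 2 of WT had both Xist and Eif2s3y, the latter at 3, while replicate 1 of GFP had neither (0.11 and 0.092). All libraries of the 4 h groups and of the later 8 h set, and replicate 1 of WT in the earlier set (Xist 0.085, Eif2s3y 19), had low Xist with Eif2s3y. In the earlier set both S40A libraries thus had high Xist, unlike WT and GFP. The 8 h fits that compare S40A with them hold no term for cell sex.

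A few single genes, picked after their values were seen, had different GFP means at 4 and 8 h, although library sets and times coincide and cannot be separated. Fabp7, a lipid carrier of radial glia, stood at 211 ± 19.4 scaled FPKM with GFP at 4 h (n = 2) and 97.4 ± 50.1 at 8 h (n = 4). Top2a, a topoisomerase of dividing cells, stood at 15.0 ± 4.76 and 2.60 ± 1.22, Egfr at 6.84 ± 1.04 and 1.38 ± 0.0885, and Pdgfra, a marker of oligodendrocyte precursors, at 3.62 ± 0.934 and 1.18 ± 0.435. Arc, a synaptic protein made after depolarization, had lower means at 4 h, 15.7 ± 6.86 against 59.6 ± 21.8. Gfap, an astrocyte filament, also had a lower mean at 4 h, 2.79 ± 1.95 against 11.8 ± 9.37.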
